A study of Mus musculus with 8 samples.

How the data were processed

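RNA-seq was carried out on total RNA of long-term haematopoietic stem cells (Lin-/cKit+/Sca1+/CD48-/CD150+) sorted from bone marrow of WT and Cx43KO mice. There were 8 libraries in 4 groups of 2: each genotype at 0 h and after 48 h of culture. Per the labels, libraries were made with the Illumina TruSeq RNA kit and sequenced on an Illumina HiSeq in paired reads of 75 bases. The read number reached is not in the files, so depth is unknown and no counting interval is given. Nothing in the labels says that the replicates came from separate animals.

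The authors deposited 1 table for 0 h and 1 for 48 h, each with a value per library for 28339 gene IDs. As deposited, the log2 values are the log2 of a normalised level plus 1, as the values themselves and the fold column show. The sums with the log undone ran from 668805 to 825199 per library. The normalised unit is not given in the sources used here. Nor are the read counter, the annotation or any filter. The submitters' processing notes name TopHat and the mm10 genome with no version or role. Per the file headers, the authors' p-value columns hold an unadjusted and an adjusted p-value of their test between genotypes and of an ANOVA. The model behind them is not given in the sources used here. These columns were only counted at 0.05: 808 genes at 0 h and 959 at 48 h by the unadjusted test, 0 and 0 by its adjusted p, 720 and 894 by the unadjusted ANOVA, and 9 and 0 by the adjusted ANOVA.

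The deposited log2 values (pseudocount 1) were analysed without further scaling in R 4.3.3 with limma 3.58.1, with a trend of the variance on mean expression. Planning had assumed read counts. Since the files hold log2 values, limma took the place of a model of counts, and the alternatives that need counts were not run. Genotypes were compared at 0 h and at 48 h within each table (4 libraries each). The change from 0 h to 48 h in each genotype and the genotype-by-time interaction were fitted in all 8 libraries. That second fit spans the tables and assumes that values were normalised library by library, since no scaling common to a table was seen in them. Had the tables been normalised separately, the plan was not to compare times. Genes with a mean level of at least 1 over the libraries fitted were tested: 14081 at 0 h, 12542 at 48 h and 13605 over time. P-values were adjusted by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. With 2 libraries per group the smallest exact two-sided p for a single gene is 0.333, so single genes were tested by limma alone.

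Lists of genes (37 fixed) with at least 5 measured members were tested with camera, from limma, at its preset inter-gene correlation of 0.01 and adjusted over the lists. The median log2 change of a list describes its size, and the test compares the statistics of its members with those of all other genes. The tests were repeated with the correlation estimated from the residuals and with fry, also from limma, which tests a list without reference to other genes. With an estimated correlation camera also uses only the residual degrees of freedom, 2 within a table and 4 in the fit of all 8 libraries. A call can be lost for that reason alone. For DNA replication over time in WT the estimate was -0.015, below the preset value. Its unadjusted camera p still rose from 3.54e-07 to 0.0047. The groups, comparisons, threshold, lists, naming rule and most alternatives were set before the data were examined.

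Genes were named by a rule. Gja1 was always named. In each comparison the 10 largest changes in each direction were to be named among genes past an adjusted p of 0.05, with groups that did not overlap and a mean level of at least 1, leaving out predicted and unnamed genes. Where none passed, the 5 smallest p in each direction were named and said not to pass. Up to 4 members with the smallest p were named for each list described, and sex-linked genes were checked per library. Gm15459, Gm13841, Hspa8, Jun, Zfp36 and Hspa1a, S100a8 at 0 h, Tpx2 over time in Cx43KO and Ddx3y fall outside the rule or beyond its comparison and were chosen after their values were seen. Of the IDs, 26940 are in GENCODE M21, which supplied positions on GRCm38, 713 have no symbol and 5782 are at 0 in every library.

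Alternatives tried were pseudocounts of 0.1 and 5, no filter, a mean level of at least 5, median-ratio scaling, no variance trend, only the 4 libraries of the groups compared, thresholds of 0.1 and of an added log2 change of 1, each library left out in turn, and the replicate number, or the label prefix, as a block. Sample weights, protein-coding genes only, all 8 libraries for the genotype comparisons, and leaving out both 0 h replicate 1 libraries were added after the data were examined. The labels number the replicates 1 and 2 in every group. The differences between replicates correlated at 0.01 to 0.25 between groups across genes, which are not independent. The largest value, 0.25, was between the WT and Cx43KO groups at 0 h. There both replicate 2 libraries were high in immediate early genes (mean scores 3.60 and 3.97), so a difference by replicate number was shared. Its origin was not established, so libraries were not paired in the main fits, and this shared difference counts there as spread.

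The methods were tested on simulated data with the group sizes and spread of these libraries and 50 changed genes at each size. Of 50 genes changed by 4 on the log2 scale limma recovered 30 at 0 h, 50 at 48 h, 44 over time in WT, 45 over time in Cx43KO and 22 in the interaction. Of 50 changed by 1 it recovered 0, 4, 2, 0 and 0. It made between 3 and 10 false calls. A list of 25 genes shifted by 1 was called in each comparison, and 0 of the unshifted lists were. The simulated genes varied independently and the lists were random. False calls of lists whose members move together, or through 1 deviating library, were therefore not measured. As a further check at 48 h, each library's deviations from the mean log2 values of the genes were fitted by a smooth trend on transcript length and mean expression. That trend was removed and the lists were tested again. Transcript sequences were compared with BLAST+ 2.17.0, and figures were drawn with Python 3.11.15 and matplotlib 3.10.9. No deposited library was left out.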

Results

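RNA-seq was carried out on long-term haematopoietic stem cells (HSC), the self-renewing cells at the top of blood formation, sorted from mouse bone marrow. Cells came from wild-type (WT) mice and from mice labelled as connexin 43 knockout (Cx43KO). Connexin 43, encoded by Gja1, is a protein of gap junctions, the channels that join the cytoplasm of neighbouring cells. Each genotype was profiled as freshly isolated quiescent cells (0 h) and as dividing cells after 48 h of culture with stem cell factor and thrombopoietin, with 2 libraries in each of the 4 groups. Nothing in the labels says that the libraries of a group came from separate animals, so a spread between animals was not established. The limma p-values of single genes measure the spread between these libraries. The camera p-values at the preset correlation compare list members with other genes, so 1 deviating library can make them small. The repeats with an estimated correlation rest on 2 or 4 residual degrees of freedom, so a lost call there need not come from correlation. The values are log2 of a normalised level plus 1, and "level" below is that value with the log undone. Read depth is unknown from these values, and between 15633 and 19646 genes were above 0 in a library.

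The 0 h libraries were less alike than the cultured ones. Across genes, the correlation of log2 values between the libraries of a group was 0.694 for WT 0 h and 0.777 for Cx43KO 0 h, against 0.937 for WT 48 h and 0.932 for Cx43KO 48 h. Immediate early genes and neutrophil genes were far higher in both 0 h replicate 2 libraries. Jun was at 323 and 411 in replicate 2 of WT and Cx43KO and at 2.62 and 0.97 in replicate 1. S100a8, a neutrophil granule protein gene, was at 3351 and 804 against 50.2 and 77.5. WT 0 h replicate 1 held 273 tissue-restricted genes (olfactory receptor, keratin and similar families) above a level of 0.1, against 41 to 57 in the other libraries. Cx43KO 0 h replicate 1 had a median correlation of 0.912 with the 48 h libraries and of 0.777 with the other 0 h libraries. The other 0 h libraries also lay closer to the 48 h libraries by this measure. WT replicate 1 was at 0.831 against 0.729, WT replicate 2 at 0.739 against 0.729 and Cx43KO replicate 2 at 0.792 against 0.772. The mRNAs of the mitochondrial genome made up 24.1% to 38.2% of the summed level of a library, highest in WT 0 h replicate 2.

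Gja1 (ENSMUSG00000050953; chromosome 10, 56377330 to 56402513, plus strand, GRCm38) separated the genotypes at 48 h and not at 0 h. At 48 h its level was 4.25 ± 0.90 in WT and 1.14 ± 0.17 in Cx43KO (SD, n = 2 each), a log2 difference of -1.28 (SE 0.39) that limma did not call over all genes (adjusted p = 0.995). At 0 h the level was 1.10 ± 0.24 in WT and 1.25 ± 0.59 in the libraries labelled Cx43KO, a log2 difference of 0.08 (SE 1.02, limma adjusted p = 0.9997). Gja1 in WT 0 h was near the filter level of 1 and no higher than in Cx43KO at 48 h. It could therefore not test the labels at 0 h, and those libraries are called by their labels. Gm15459, a gene examined only after its values were seen, did split the 0 h libraries as their labels do, with 56.5 and 205 in WT and 3.13 and 2.80 in Cx43KO. In WT cells Gja1 was 1.32 (SE 0.59) higher on the log2 scale at 48 h than at 0 h (adjusted p = 0.584). As a list, connexins and pannexins were not called in any comparison, but were over time in Cx43KO with only the 4 libraries compared, without WT 0 h replicate 2 and without Cx43KO 0 h replicate 1. At 48 h 5 of 6 measured members were lower in Cx43KO (median log2 difference -0.04, camera adjusted p = 0.813), and at 0 h 5 of 8 were lower (-0.08, adjusted p = 0.569).

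**Figure D1:**
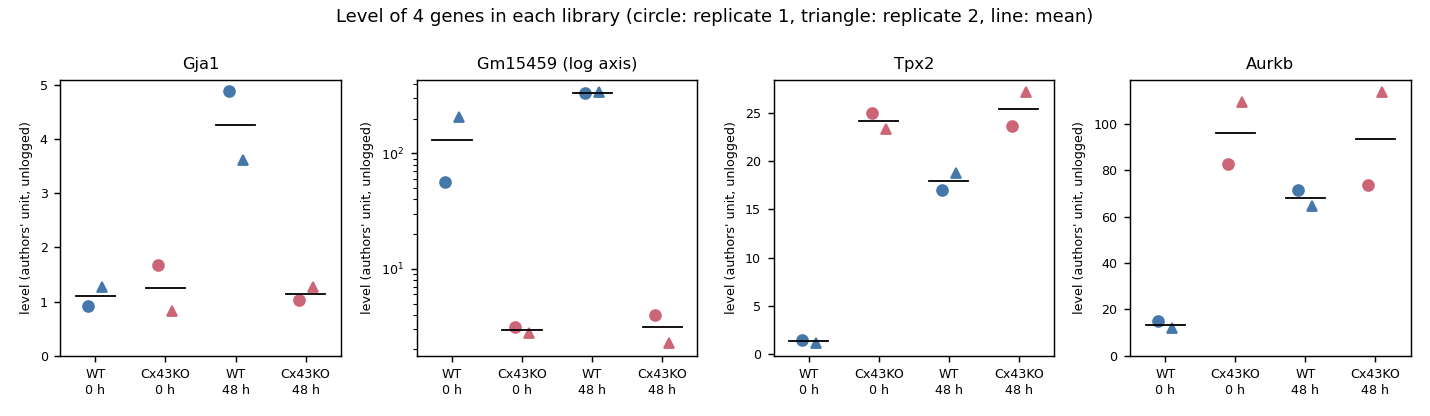
Level of Gja1, Gm15459, Tpx2 and Aurkb in each of the 8 libraries (vertical axes, authors' unit with the log undone; log axis for Gm15459), by genotype and hours of culture (horizontal axes). Circles are replicate 1, triangles replicate 2 and lines group means; Gja1 separates the genotypes at 48 h only, Gm15459 at both times, and Tpx2 is at 1.51 and 1.12 in the WT 0 h libraries against 17.0 to 27.1 in all others.

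The first comparison asked how quiescent HSC labelled Cx43KO differed from WT. Genes of mitosis were higher in the 0 h libraries labelled Cx43KO than in WT 0 h libraries. Of the 25 list members, 24 were higher, with a median log2 difference of 0.79 (camera adjusted p = 1.12e-05, but adjusted p = 0.879 with an estimated correlation). Tpx2, a spindle assembly factor (chromosome 2, 152847964 to 152895321), was at 1.31 ± 0.28 in WT and 24.1 ± 1.11 in Cx43KO, a log2 difference of 3.45 (SE 0.84). Aurkb, the mitotic kinase Aurora B (chromosome 11, 69045647 to 69051664), was at 13.5 ± 1.93 and 96.1 ± 18.8. Ube2c, a ubiquitin-conjugating enzyme of the anaphase-promoting complex, was at 44.9 and 13.5 in WT and at 220 and 116 in Cx43KO. Cdk1 was at 26.9 and 13.4 against 134 and 27.2. Adjusted over the list alone, 2 members passed. The groups did not overlap for 16 members, where chance alone gives 33.3% of genes.

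All 13 mRNAs encoded by the mitochondrial genome were lower in the 0 h libraries labelled Cx43KO, with a median log2 difference of -0.48 (camera adjusted p = 1.01e-07, but adjusted p = 0.879 with an estimated correlation). Among them mt-Nd4, a complex I subunit, had a log2 difference of -0.48 (SE 0.30) and mt-Co3, a subunit of cytochrome oxidase, had a log2 difference of -0.58 (SE 0.37). Cytosolic ribosomal protein genes were higher for 31 of 34 members (median 0.46, camera adjusted p = 0.0139, but adjusted p = 0.879 with an estimated correlation). Rpl18 had a log2 difference of 0.81 (SE 0.48) and Rps15 of 0.58 (SE 0.41). Adjusted over the list alone, 0 members of these lists passed limma, and 0 of either had an unadjusted p under 0.05. Complex I genes encoded in the nucleus (median 0.35, 26 of 36 higher, adjusted p = 0.238) and DNA replication genes (0.39, 22 of 26 higher, adjusted p = 0.238) were not called. Nor were MYC and ribosome biogenesis (0.49, 22 of 25 higher, adjusted p = 0.0511) or HSC identity and quiescence (-0.06, 16 of 28 lower, adjusted p = 0.176). Within the last list Procr, the surface marker EPCR of HSC, was at 39.2 and 74.5 in WT and at 6.47 and 28.1 in Cx43KO (log2 difference -1.90, SE 0.87).

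Gene by gene, limma called 0 of 14081 genes at 0 h. An unadjusted p under 0.05 was reached by 318, against 704 by chance alone. The authors' deposited table covers 28339 gene IDs and lists 808 of them under 0.05 by its unadjusted p and 0 by its adjusted p. The 704 is for the 14081 genes tested here and is not the chance number for those IDs. The replicate number as a block takes up the difference shared by the 0 h replicate 2 libraries, though its origin was not established. With it limma called 11 genes, Ube2c, Ankef1 and Tsix among them. With the same block 5 lists were called in place of 3, with MYC and mitochondrial import added. The genes with the smallest p, none past the threshold, were Rps2-ps10, Tpx2, Aurkb, Inpp5e and Lepre1 among those higher in Cx43KO and Ankef1, Eif2s3y, Rnf121, Kdm5d and Dear1 among those lower. Rps2-ps10 is a ribosomal pseudogene that can share reads with its parent gene, so its value is uncertain. Ankef1 was at 74.1 and 116 in WT and at 10.6 and 12.01 in Cx43KO. Eif2s3y and Kdm5d are Y-linked. Eif2s3y was at 18.9 and 15.0 in WT 0 h, 0.49 and 1.03 in Cx43KO 0 h, 0.33 and 0.45 in WT 48 h, and 23.4 and 1.43 in Cx43KO 48 h. Gm13841, a pseudogene outside the naming rule and chosen after its values were seen, had the smallest adjusted p (0.0661, log2 difference -6.86, SE 0.80). The median of all genes was 0.21 higher in the libraries labelled Cx43KO, and 0.01 after median-ratio scaling, under which the ribosomal protein list had a median of 0.23 and was no longer called. The number of lists called was 3 with all libraries, 11 without WT 0 h replicate 1 and 17 without Cx43KO 0 h replicate 2. Without Cx43KO 0 h replicate 1 the mitosis list lost its call: its median was 0.83 but that of all genes was 0.53, so the excess over all genes was 0.30. Ribosomal proteins then had a median of 0.26, below that of all genes. Without WT 0 h replicate 2 ribosomal proteins (0.31) also lost their call and lay below all genes (0.41). Mitochondrial mRNAs lost their call with no filter and without a variance trend, and ribosomal proteins without a variance trend and with all 8 libraries in the fit.

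The second comparison asked the same of dividing HSC after 48 h of culture. As lists, nuclear genes of oxidative phosphorylation and cytosolic ribosomal protein genes were called lower in Cx43KO, through 1 of its 2 libraries. Complex I of the respiratory chain was lower for 32 of 36 members, with a median log2 difference of -0.36 (camera adjusted p = 3.71e-05, but adjusted p = 0.931 with an estimated correlation). Complexes II to IV were lower for 22 of 25 members (-0.29, adjusted p = 0.00875), ATP synthase for 13 of 15 (-0.36, adjusted p = 0.0479) and ribosomal proteins for 32 of 34 (-0.30, adjusted p = 0.0248), each with adjusted p = 0.931 with an estimated correlation. These differences lay in Cx43KO replicate 2. Replicate 1 was near WT for complex I and above both WT libraries in mean score for the other 3 lists. Ndufa6, a complex I subunit, was at 66.4 and 78.4 in WT and at 52.2 and 24.3 in Cx43KO replicates 1 and 2. Cox4i1, a subunit of cytochrome oxidase, was at 255 and 286 against 283 and 101, and Rps15 at 1856 and 2027 against 1968 and 851. In Cx43KO 48 h replicate 2 the 10 most abundant genes took 49.2% of the summed level, against 36.8% in replicate 1 and 43.0% and 39.9% in WT. The mRNAs of the mitochondrial genome took 33.6% there, against 24.1% to 27.2% in the other 48 h libraries. With a trend on transcript length and expression removed, complexes II to IV (-0.11), ATP synthase (-0.18) and ribosomal proteins (-0.09) were no longer called, complex I (-0.27) was, and mitochondrial mRNAs (0.43) were called higher.

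Rplp0, the acidic ribosomal stalk protein gene (chromosome 5, 115559467 to 115563727), moved against its list: 108 ± 5.50 in WT and 281 ± 46.4 in Cx43KO, a log2 difference of 1.37 (SE 0.25). It was the 1 ribosomal protein gene that passed limma adjusted over the list alone, and it was not called over all genes (adjusted p = 0.995). Adjusted over the list alone, 0 members passed for complex I (4 with an unadjusted p under 0.05), complexes II to IV (0) and ATP synthase (0). Mitosis (11 of 25 higher, median -0.00, adjusted p = 0.825), DNA replication (14 of 26 higher, 0.03, adjusted p = 0.825) and HSC identity genes (14 of 26 higher, 0.02, adjusted p = 0.849) were not called. Neutrophil genes were not called either (6 of 8 lower, median -1.29, adjusted p = 0.0563), but were with no filter, with the replicate block, with protein-coding genes only and without WT 48 h replicate 1. The gap lay mostly in WT 48 h replicate 2. Among them S100a9 was at 8.23 and 135 in WT and at 0.31 and 0 in Cx43KO, and S100a8 at 4.88 and 106 against 0 and 2.34. Erythroid markers (5 of 7 lower, median -0.16, adjusted p = 0.0780) were not called, but were without WT 48 h replicate 2. Adjusted over the list alone, 2 members passed limma. Among the members Alas2, which makes the first intermediate of haem, was at 7.34 and 6.14 in WT against 2.73 and 1.46 in Cx43KO. Hbb-b1 was at 22.3 and 10.2 against 3.53 and 5.28. Hbb-b1 has near-identical globin copies and is uncertain.

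Over all 12542 genes tested at 48 h, limma called 1, Gm15459 (ENSMUSG00000083840), named here although the naming rule leaves out predicted genes, because it was the only call. It was at 337 ± 1.74 in WT and 3.14 ± 1.23 in Cx43KO (log2 difference -6.38, SE 0.29, adjusted p = 0.00364). The 0 h libraries were split the same way. In the annotation the transcript of a gene with this name, under another ID, matches that of the heat shock protein gene Hspa8 at 99.7% of 1941 aligned bases, so its reads can be shared with Hspa8. Hspa8 was at 551 and 520 in WT 48 h and at 1086 and 740 in Cx43KO 48 h. An unadjusted p under 0.05 was reached by 502 genes, against 627 by chance alone. The authors' deposited table covers 28339 gene IDs and lists 959 of them under 0.05 by its unadjusted p and 0 by its adjusted p. The 627 is for the 12542 genes tested here and is not the chance number for those IDs. The named genes with the smallest p, none past the threshold, were Rplp0, Hist1h4a, Arap2, Vamp2 and Hyi among those higher in Cx43KO and Xlr3b, Slc19a2, Hist1h4m, Tmsb15b1 and Acbd4 among those lower. Slc19a2, a thiamine transporter, was at 14.3 ± 1.86 in WT and 2.81 ± 0.89 in Cx43KO (log2 difference -2.02, SE 0.33, adjusted p = 0.995). The histone genes Hist1h4a and Hist1h4m can share reads with their copies and are uncertain. Without Cx43KO 48 h replicate 2 complex I (-0.05) was no longer called, and complexes II to IV and ATP synthase turned to 0.08 and 0.09. Ribosomal proteins turned to 0.10 and were then called higher. Without WT 48 h replicate 1 limma called 0 genes and without WT 48 h replicate 2 it called 4. ATP synthase also lost its call with pseudocount 5, no filter, a mean level of at least 5, no variance trend or median-ratio scaling, and ribosomal proteins with no filter or the replicate block. Leaving out either WT 48 h library ended the calls of complexes II to IV (-0.30 and -0.26), ATP synthase (-0.29 and -0.42) and ribosomal proteins (-0.32 and -0.31).

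The third comparison followed WT cells from quiescence into division. As a list, genes of mitosis were called higher at 48 h. All 25 members were higher, with a median log2 change of 1.32 (camera adjusted p = 2.70e-18, but adjusted p = 0.0558 with an estimated correlation), and 15 members passed limma adjusted over the list alone. Tpx2 was at 1.31 ± 0.28 at 0 h and 17.9 ± 1.23 at 48 h, and Ube2c at 44.9 and 13.5 against 278 and 246. Ccnb1, the mitotic cyclin B1, was at 5.44 and 7.62 against 43.5 and 42.4. Also called higher as lists were DNA replication (23 of 26 higher, median 0.70, adjusted p = 3.19e-06), MYC and ribosome biogenesis (22 of 25, 0.69, 2.01e-05) and nucleotide and one-carbon synthesis (21 of 21, 0.72, 3.33e-05), each with adjusted p = 0.0733 with an estimated correlation. Mcm7, part of the replicative helicase, was at 37.1 and 31.3 at 0 h and at 92.2 and 82.7 at 48 h, and Rrm2, a ribonucleotide reductase subunit, at 17.4 and 27.8 against 60.3 and 61.2.

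Mitochondrial and biosynthetic lists were called higher in WT cells as well, although of their members only Ndufa12 of complex I and 2 of the mitochondrial ribosome passed limma over the list alone. All 20 genes of mitochondrial import and chaperones were higher at 48 h (median 0.75, adjusted p = 1.85e-06), with 25 of 27 of the mitochondrial ribosome (0.71, 2.07e-05), 15 of 20 of cholesterol synthesis (0.61, 0.00452) and 15 of 23 of antioxidant defence (0.27, 0.0489), each with adjusted p = 0.324 with an estimated correlation. Hspd1, the mitochondrial chaperonin, was at 155 and 76.1 at 0 h and at 325 and 314 at 48 h. Complex I genes were higher for 30 of 36 members (0.70, 2.14e-06), complexes II to IV for 22 of 25 (0.65, 8.66e-05), ATP synthase for 14 of 15 (0.73, 7.36e-04) and type I interferon response genes for 20 of 24 (0.66, 0.00137), each with adjusted p = 0.535 with an estimated correlation. The mRNAs encoded in the mitochondrial genome were called lower, with 10 of 13 lower (-0.36, adjusted p = 0.0378, but adjusted p = 0.535 with an estimated correlation). Ribosomal protein genes were higher for 30 of 34 (0.43, 8.68e-04, but adjusted p = 0.576 with an estimated correlation).

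As a list, genes of HSC identity and quiescence were called lower at 48 h in WT cells (25 of 28 members lower, median -1.14, adjusted p = 3.22e-05). So were immediate early genes (21 of 21, -2.77, 1.58e-05), neutrophil and granule genes (15 of 18, -1.66, 0.00115) and B lymphoid markers (8 of 9, -1.39, 0.00456), each with adjusted p = 0.535 with an estimated correlation. NF-kB and inflammatory response genes were called lower, with 15 of 19 lower (-1.06, 0.0489, but adjusted p = 0.672 with an estimated correlation). Procr was at 39.2 and 74.5 at 0 h and 12.4 and 12.3 at 48 h, and Itga2b, which encodes CD41, at 119 and 101 against 16.4 and 37.0. Ly6a, the Sca-1 antigen used in the sort, was at 103 and 19.3 at 0 h and 204 and 309 at 48 h. The transcription factor gene Egr1, a member of both the HSC and the immediate early list, was at 89.9 and 718 at 0 h and 12.04 and 15.7 at 48 h. S100a8 stood at 50.2 and 3351 at 0 h and at 4.88 and 106 at 48 h.

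In all, 19 of 36 lists were called over time in WT. With an estimated correlation, a test with 4 residual degrees of freedom, 0 were. Gene by gene limma called 0 of 13605, with 1153 at an unadjusted p under 0.05 (chance alone gives 680). Smallest in p, none past the threshold, were Tpx2, Bex6, Slc19a2, Ube2c and Zc3h18 among genes higher at 48 h and Ankef1, Upp1, Obsl1, Tmsb15l and Ifitm7 among genes lower. The comparison of times spans 2 deposited tables and assumes that each library was normalised by itself. The Y-linked genes Eif2s3y and Kdm5d split the WT libraries by time as well, so sex of the animals was not separated from time in WT. Without WT 0 h replicate 2, 9 lists were called in place of 19, and those that lost their call included HSC identity (-0.26), immediate early genes (-0.29), neutrophil genes (-0.01), B lymphoid markers (-0.03), NF-kB (0.19), the mitochondrial ribosome (0.37), ribosomal proteins (0.32), cholesterol synthesis (0.45), antioxidant defence (0.24) and mitochondrial mRNAs (-0.21). Without WT 0 h replicate 1 limma called 3 genes, and the interferon (-0.06) and mitochondrial mRNA (-0.50) lists lost their calls. So did interferon (0.32) and mitochondrial mRNAs (-0.38) without WT 48 h replicate 2, and antioxidant defence (0.29) and NF-kB (-1.19) without WT 48 h replicate 1. Calls also ended for mitochondrial mRNAs without either Cx43KO 0 h library, antioxidant defence without Cx43KO 0 h replicate 2 and NF-kB without either Cx43KO 48 h library, where the medians stayed at -0.36, 0.27 and -1.06. Choices of processing ended some calls too. Mitochondrial mRNAs lost theirs with pseudocount 0.1, no filter, no variance trend, median-ratio scaling or sample weights. Antioxidant defence did with pseudocount 0.1, no variance trend, median-ratio scaling, the block by label prefix, sample weights or protein-coding genes only. NF-kB did with either pseudocount, no filter, a mean level of at least 5 or no variance trend, and B lymphoid markers with a mean level of at least 5.

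**Figure D2:**
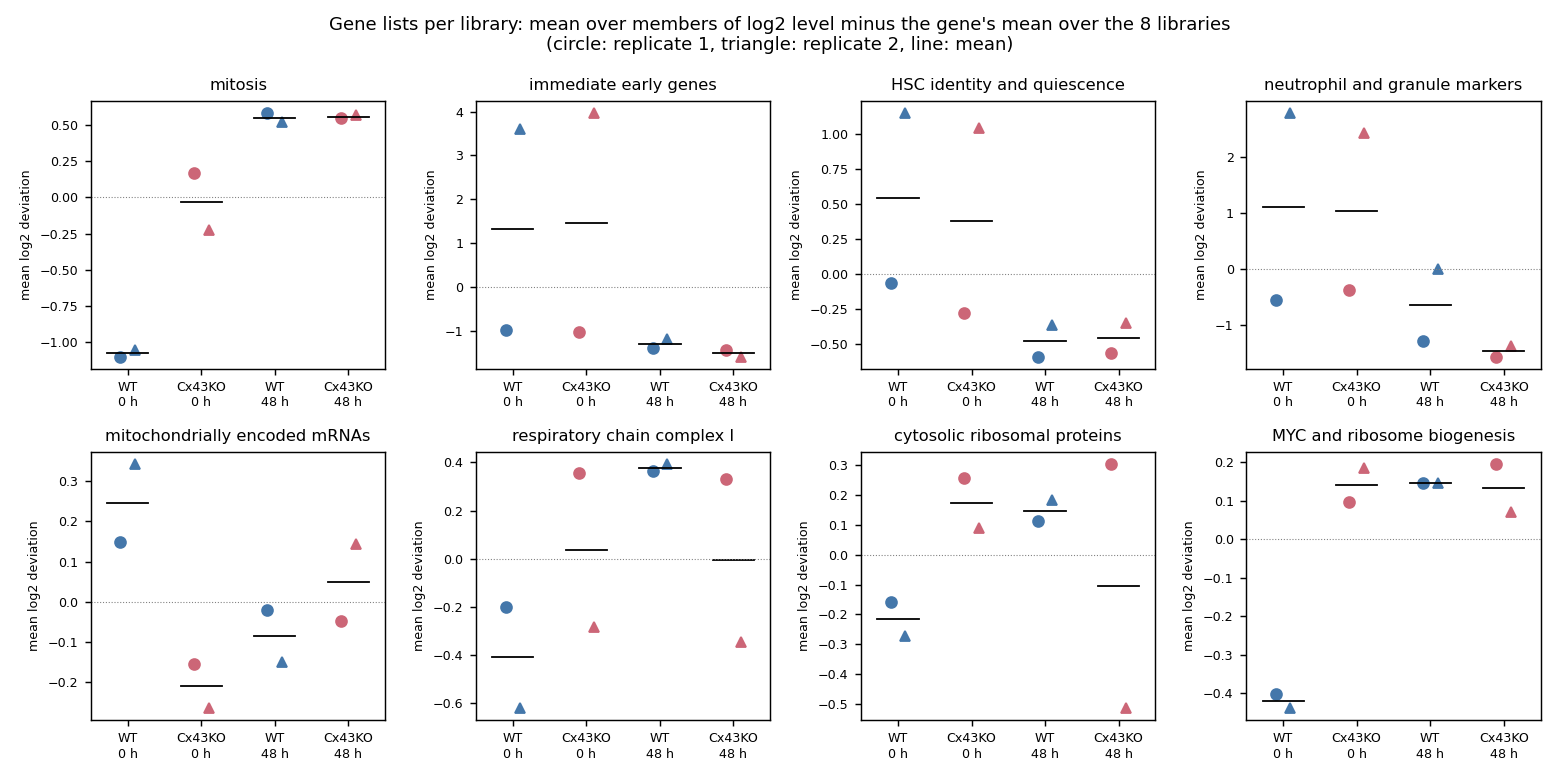
For 8 gene lists, the mean over members of the log2 level minus the gene's mean over the 8 libraries (vertical axes, log2) in each library, by genotype and hours of culture (horizontal axes). Scores are not adjusted for the shift of all genes in a library. The median shift was -0.24 and 0.15 in WT 0 h and -0.15 and 0.54 in Cx43KO 0 h, so much of the score of Cx43KO 0 h replicate 2 is shared by all genes. Circles are replicate 1, triangles replicate 2 and lines group means; mitosis genes are at -1.10 and -1.05 in WT 0 h against 0.17 and -0.23 in Cx43KO 0 h, immediate early genes are at 3.60 and 3.97 in the 0 h replicate 2 libraries, and complex I is at -0.34 in Cx43KO 48 h replicate 2 against 0.33 in replicate 1.

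The fourth comparison followed Cx43KO cells over the same interval, with the 0 h libraries taken by their labels. Calls here are relative to all genes, whose median change was -0.29. Called higher as lists were mitosis (23 of 25 members higher, median log2 change 0.52, camera adjusted p = 4.36e-10), DNA replication (18 of 26, 0.29, 3.83e-05) and nucleotide and one-carbon synthesis (17 of 21, 0.30, 1.25e-04), each with adjusted p = 0.111 with an estimated correlation. Tpx2 was at 24.1 ± 1.11 at 0 h and 25.4 ± 2.44 at 48 h, and Ccnb1 at 17.1 and 13.8 against 46.0 and 32.8. Aurka, the mitotic kinase Aurora A, was at 9.83 and 4.56 against 27.3 and 17.3, and Rrm2 at 27.8 and 22.1 against 86.1 and 84.5. The mitochondrial ribosome (19 of 27 higher, 0.16, adjusted p = 0.00160) and cholesterol synthesis (13 of 20, 0.15, 0.0124) were called too, each with adjusted p = 0.468 with an estimated correlation. Of these 5 lists 0 members passed limma over the list alone, and unadjusted p under 0.05 was reached by 3 mitosis, 2 DNA replication, 1 cholesterol and 0 other members. Mitochondrial import was called with 13 of 20 higher (0.21, 0.00144, but adjusted p = 0.690 with an estimated correlation), and MYC and ribosome biogenesis with 15 of 25 higher (0.11, 0.0344, but adjusted p = 0.433 with an estimated correlation). Mitochondrially encoded mRNAs were called with 9 of 13 higher (0.32, 2.28e-04, but adjusted p = 0.452 with an estimated correlation). Type I interferon response genes were called higher although their median was -0.04, so test and median differ in sign (11 of 24 higher, adjusted p = 0.0499, but adjusted p = 0.822 with an estimated correlation). Complex I (median 0.01, 18 of 36 higher, adjusted p = 0.155) and ribosomal protein genes (-0.34, 29 of 34 lower, adjusted p = 0.230) were not called.

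As lists, immediate early genes of Cx43KO cells were called lower at 48 h with 21 of 21 members lower (median -3.14, adjusted p = 2.41e-07, but adjusted p = 0.725 with an estimated correlation) and neutrophil and granule genes with 17 of 18 (-2.19, 2.39e-05, but adjusted p = 0.704 with an estimated correlation). HSC identity genes were called lower with 24 of 28 (-0.73, 0.0218) and NF-kB genes with 17 of 19 (-1.27, 0.0205), each with adjusted p = 0.852 with an estimated correlation. Monocyte, macrophage and dendritic cell markers were called lower with 12 of 13 (-1.30, 0.0370, but adjusted p = 0.822 with an estimated correlation). Egr1 was at 76.9 and 595 at 0 h and 12.2 and 15.7 at 48 h, S100a9 at 34.7 and 1009 against 0.31 and 0, and Mpo, the myeloperoxidase gene, at 3.03 and 93.5 against 0.14 and 0.33. Hlf, a transcription factor of HSC, was at 88.7 and 124 at 0 h and 51.4 and 31.5 at 48 h.

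Of 36 lists, 14 were called over time in Cx43KO, and with an estimated correlation 0 were. Gene by gene limma called 0 of 13605 genes, with 474 at an unadjusted p under 0.05 (chance alone gives 680). The smallest p values, none past the threshold, were those of Ifi27l2a, Phf11d, Yipf2, Rrm2 and Zfp668 among genes higher at 48 h and of Rps2-ps10, Cpt1b, Vps8, Egr2 and Upp1 among genes lower, with an adjusted p of 0.0827 for the pseudogene Rps2-ps10. The median of all genes changed by -0.29, and by 0.01 after median-ratio scaling, under which the interferon list lost its call (median 0.26). It also did with pseudocount 0.1, no filter or no variance trend. Monocyte markers lost theirs with pseudocount 5, no filter or a mean level of at least 5, HSC identity with a mean level of at least 5, MYC with no filter or no variance trend, and mitochondrial mRNAs and cholesterol synthesis with no filter. Without Cx43KO 0 h replicate 2, 2 lists were called in place of 14, and of those named here mitosis (0.25), DNA replication (0.24), nucleotide synthesis (0.28), the mitochondrial ribosome (0.09), cholesterol synthesis (-0.00), mitochondrial import (0.05), MYC (0.09), mitochondrial mRNAs (0.24), interferon (0.06), immediate early (-0.23), neutrophil (-0.23), HSC identity (-0.06) and monocyte markers (-0.07) lost their call and NF-kB turned to 0.04. Without Cx43KO 0 h replicate 1, 21 lists were called. Without Cx43KO 48 h replicate 1 the mitochondrial ribosome (-0.01), mitochondrial import (0.05), HSC identity (-0.60), MYC (0.03), cholesterol synthesis (-0.09) and monocyte markers (-0.64) lost their call. Without Cx43KO 48 h replicate 2 the interferon list did (-0.22), and without WT 0 h replicate 2 the NF-kB list did (-1.39).

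The genotype-by-time interaction asked whether the change from 0 h to 48 h differed between genotypes. For mitosis genes the change was smaller in Cx43KO at 24 of 25 members (median log2 interaction -0.83, camera adjusted p = 8.00e-06, but adjusted p = 0.454 with an estimated correlation). Tpx2 had an interaction of -2.97 (SE 0.63), Aurkb of -2.31 (SE 0.59) and Ube2c of -2.68 (SE 0.81). Adjusted over the list alone, 2 mitosis genes passed. The mRNAs of the mitochondrial genome went the other way at 13 of 13 (0.59, adjusted p = 4.84e-06, but adjusted p = 0.454 with an estimated correlation). MYC and ribosome biogenesis genes were lower at 24 of 25 (-0.51, 0.0439, but adjusted p = 0.454 with an estimated correlation). Complex I genes were lower at 30 of 36 (-0.62, 0.00131) and ribosomal proteins at 32 of 34 (-0.74, 1.87e-04), each with adjusted p = 0.790 with an estimated correlation. Ndufa12 of complex I had an interaction of -3.16 (SE 0.83), and Rplp0 again went against its list at 1.76 (SE 0.60). Gja1 had an interaction of -1.36 (SE 0.84, adjusted p = 0.999).

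For single genes limma called 0 interactions of 13605, with 432 at an unadjusted p under 0.05 (chance alone gives 680). The smallest p values, none past the threshold, were those of Eif2s3y, Ankef1, Kdm5d, Lrrc66 and Krt19 among positive and of Rps2-ps10, Bex6, Cpt1b, Tpx2 and Zfp647 among negative interactions. The median over all genes was -0.24, and 0.02 after median-ratio scaling, under which the MYC (-0.23) and ribosomal protein (-0.46) lists lost their calls. MYC also did with no variance trend, a mean level of at least 5 or the block by label prefix, and mitochondrial mRNAs did with no filter. The 0 h side of these interactions follows the labels, which Gja1, near the filter level in WT 0 h, did not separate and Gm15459 did. Without Cx43KO 0 h replicate 1 the mitosis (-0.66), MYC (-0.44) and ribosomal protein (-0.66) lists lost their calls and complex I (-0.52) turned relative to all genes. Without WT 0 h replicate 2 complex I (-0.57), MYC (-0.44) and ribosomal proteins (-0.63) lost theirs. So did these 3 lists without Cx43KO 48 h replicate 2 (-0.37, -0.48 and -0.35) and MYC without WT 48 h replicate 1 (-0.42) or 2 (-0.52). The number of lists called was 5 with all libraries, 11 without WT 0 h replicate 1, 2 without WT 0 h replicate 2, 1 without Cx43KO 0 h replicate 1, 16 without Cx43KO 0 h replicate 2, 9 without Cx43KO 48 h replicate 1 and 2 without Cx43KO 48 h replicate 2.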

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

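The interaction tests, their repeats by other tests and the leaving out of each library were set before the data were examined, and the test of a trend with length and expression was chosen before its result was seen. The use of left-out libraries to weigh explanations and the tests on sex, Hspa8 and a strain variant were chosen after results had been seen. The difference between the times was itself tested as the interaction, and 5 gene lists were picked out because the effect of genotype at 48 h differed from that at 0 h. Their median log2 interactions were -0.62 for complex I, 0.59 for mitochondrially encoded mRNAs, -0.83 for mitosis, -0.51 for MYC and ribosome biogenesis and -0.74 for cytosolic ribosomal proteins. With an estimated correlation 0 of the 5 were called by camera, and by fry 1 was, MYC and ribosome biogenesis.

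The interaction of the mitosis genes comes from higher values at 0 h in the libraries labelled knockout. Background transcripts in WT 0 h replicate 1, the library with 273 tissue-restricted genes, were argued against as the whole cause, though only weakly: without that library the list kept a median of 0.65 and its call. That fit holds 1 WT library and takes its whole spread from the 2 Cx43KO libraries. A knockout library that resembled cultured cells stays open. Cx43KO 0 h replicate 1 correlated at 0.912 with the 48 h libraries, the highest median among the 0 h libraries. Each 0 h library, however, had a higher median correlation with the 48 h libraries than with the other 0 h libraries. WT 0 h replicate 1 was at 0.831 against 0.729. Without Cx43KO 0 h replicate 1 the list lost its call. Its median then exceeded that of all genes by 0.30, so its part cannot be told apart from a genotype effect shared by both libraries. Tpx2 was at 24.9 in that library and at 23.4 in the other, but it was named for its small p, which favours replicates that agree. Cdk1, Ube2c and Aurka were higher in that library than in the other. The mean score of the whole list was 0.17 in that library and -0.23 in the other, without adjustment for all genes. Sex of the animals also stays open, because the Y-linked gene Eif2s3y differed by -3.36 on the log2 scale at 0 h and so split the libraries as the genotype labels did. Kdm5d and Ddx3y, also Y-linked, split the 0 h libraries the same way. Uty, Y-linked as well, overlapped at 0 h (7.53 and 32.7 in WT, 2.80 and 22.5 in Cx43KO). Eif2s3y split the libraries differently at 48 h, where WT stood at 0.33 and 0.45 and Cx43KO at 23.4 and 1.43. A genotype effect on quiescence remains possible and was not separated from these.

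The low level of Gm15459 in the 4 knockout libraries may come from reads shared with its parent gene Hspa8. Hspa8 was 0.74 higher on the log2 scale in Cx43KO at 48 h (SE 0.30), where 0.70 would follow if all reads of the copy had moved to the parent. The sum of the levels of the 2 genes differed by 0.04 (SE 0.28) at 48 h. At 0 h the sum was 0.75 higher (SE 0.30), where a transfer of reads alone would leave it unchanged. The sums were 570 and 835 in WT 0 h and 1061 and 1274 in Cx43KO 0 h. The median of all genes was also 0.21 higher there. With 2 libraries per group an excess over a transfer was not established. A strain variant carried by 1 of the mouse lines is a candidate explanation for why reads would move. Linkage of it to the knockout allele is unknown: the deposited ID has no position in GENCODE M21, where a gene of the same name under another ID lies on chromosome 5 and Gja1 on chromosome 10. The lowest WT level was 14.1 times the highest Cx43KO level, a separation such a variant would also give, and without reads it cannot be told apart from a genotype effect on the copy.

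The interaction of complex I rests partly on lower values in Cx43KO at 48 h, and those may come from a single library. Without Cx43KO 48 h replicate 2 the median at 48 h was -0.047 and the list was not called. A trend with transcript length and expression level was argued against as the whole cause for complex I. With it removed the median went from -0.36 to -0.27 and the list was still called, in a fit that holds Cx43KO 48 h replicate 2. The trend explained at most 3.204% of the variance of a library's deviations from the gene means. That share is over all genes and does not measure its effect on a list. For the other lists called at 48 h the trend stays open. The same correction ended the calls of complexes II to IV (-0.11), ATP synthase (-0.18) and ribosomal proteins (-0.09), and mitochondrial mRNAs (0.43) were then called higher. Whether that library differs through its handling or through biology stays open, with 1 other library in its group. No biological explanation was tested for it.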

How the results depend on the processing

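Sample weights, protein-coding genes only, all 8 libraries for the genotype comparisons and leaving out both 0 h replicate 1 libraries were chosen after seeing the data. Alternatives set beforehand that need read counts were not run: library-size and RLE normalisation, filterByExpr, a filter on CPM and DESeq2. Of the counts of genes called under alternatives 82 stayed within 1.5 times the value reported and 16 did not; for counts of lists these were 67 and 31. Of the list directions 736 kept side and call, 203 lost the call and 6 reversed. Of the results for named genes 4126 kept their side and stayed called or uncalled, 100 gained a call, 2 lost it and 14 reversed. The main fits called only 1 gene, Gm15459 at 48 h, so nearly all of the 4126 had no call to keep. For the same reason most counts of genes were set against a main count of 0, where staying the same means 0 again and shows no stability. Ranges below are over fits with 1 library left out. In a genotype comparison the lone library of a group is then assumed to vary like the other group. The cause was not tested unless stated.

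At 0 h limma called 0 genes, but 1 at a mean level of at least 5, 11 with a replicate block, 1 at an adjusted p under 0.10 and 631 without both 0 h replicate 1 libraries, where a lone library is assumed to vary like the cultured ones. Of the lists 3 were called, against 11 with no filter, 1 without a variance trend, 5 with the replicate block, 0 without both replicate 1 libraries, 0 with an estimated correlation and 0 by fry. Leaving out 1 library gave 1 (without Cx43KO replicate 1) to 17 lists (without Cx43KO replicate 2). Gja1 at 0 h (0.08) ranged from -0.19 to 0.35 with 1 library left out, was -0.03 without WT replicate 1 and -0.31 without both replicate 1 libraries. Ribosomal proteins (0.46) ranged from 0.26 to 0.62 with 1 library left out, were at 0.23 with median-ratio scaling, and lay below all genes at 0.26, without Cx43KO replicate 1, and at 0.31, without WT replicate 2.

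At 48 h limma called 1 gene, but 0 with no filter and 0 with protein-coding genes only, which leaves out Gm15459. Leaving out 1 library gave 0 (without WT replicate 1) to 4 genes (without WT replicate 2). Of the lists 4 were called, against 0 with an estimated correlation, 0 by fry and 2 to 6 with 1 library left out. With the replicate block the count stayed at 4, but ribosomal proteins lost their call and neutrophil genes gained one. Complexes II to IV ranged from -0.62 to 0.077, ATP synthase from -0.79 to 0.088 and ribosomal proteins from -0.74 to 0.10, the upper end in each case without Cx43KO replicate 2, where Cox4i1 (range -1.41 to 0.065) and Rps15 (-1.19 to 0.021) also reversed. Gja1 kept its direction at 48 h, from -1.46 to -1.11.

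Over time in WT limma called 0 genes, but 2 with a replicate block by label prefix, 2169 without both 0 h replicate 1 libraries and 0 to 3 with 1 library left out (3 without WT 0 h replicate 1). Of the lists 19 were called, against 0 with an estimated correlation, 4 by fry (mitosis, DNA replication, MYC, nucleotide synthesis) and 9 to 19 with 1 library left out (9 without WT 0 h replicate 2).

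Over time in Cx43KO limma called 0 genes, but 1 with pseudocount 5, 2 in only the 4 libraries compared, 4 with the block by label prefix, 1 at an adjusted p under 0.10 and 1731 without both 0 h replicate 1 libraries. Of the lists 14 were called, against 0 with an estimated correlation, 0 by fry and 2 to 21 with 1 library left out. Gja1 (-0.05) ranged from -0.32 to 0.22 and was 0.094 with median-ratio scaling, 0.22 without Cx43KO 0 h replicate 1, 0.03 without Cx43KO 48 h replicate 1 and 0.22 without both replicate 1 libraries. Without Cx43KO 0 h replicate 2 the NF-kB and inflammatory response genes, median log2 change 48 h against 0 h in Cx43KO (0.043, range -2.74 to 0.043), Gm15459 (-0.031), Mrpl12 (-0.45, to 1.76), Fen1 (-0.053, to 1.98) and Rrp9 (0.20, from -3.40) reversed. Gm15459 (range -0.28 to 0.34) also did without Cx43KO 48 h replicate 1.

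Of the lists 5 were called in the interaction, against 14 with no filter, 3 with median-ratio scaling, 8 with the replicate block, 0 without both replicate 1 libraries, 0 with an estimated correlation, 1 by fry and 1 to 16 with 1 library left out. Complex I ranged from -1.01 to -0.37 and was at -0.52 without Cx43KO 0 h replicate 1, which lies on the other side of all genes. Depth is unknown from the files, so what it limits was not measured.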

Other observations

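The tables also assign genes to WikiPathways groups, and these were tested with camera after the fixed lists had been seen. Over time in WT 11 of 140 groups were called, and with an estimated correlation 0 were. Among them the 61 genes of proteasome degradation had a median log2 change of 0.44 (48 higher, adjusted p = 3.13e-05, but adjusted p = 0.990 with an estimated correlation). In Cx43KO the same group had a median of 0.16 (40 higher, adjusted p = 0.00654, but adjusted p = 0.991 with an estimated correlation). Translation factors had a median of 0.32 in WT (35 of 51 higher, adjusted p = 0.0214, but adjusted p = 0.990 with an estimated correlation). The larger set of cytoplasmic ribosomal proteins had medians of 0.44 at 0 h and -0.38 at 48 h between genotypes, and of -0.74 in the interaction (91 of 95 lower, adjusted p = 2.29e-08, but adjusted p = 0.9996 with an estimated correlation). For the fixed ribosomal protein list the 48 h difference lay in Cx43KO replicate 2. No library was left out in the tests of these groups.

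In a principal component analysis the first component took 40.1% of the variance and set both 0 h replicate 2 libraries (105 and 93.4) apart from the other 6 (-39.0 to -24.2). In those 2 libraries Zfp36, an immediate early gene whose product promotes decay of inflammatory mRNAs, was at 816 and 568 against 11.4 and 10.1 in the other 0 h libraries, and Hspa1a, a heat shock protein gene, at 115 and 300 against 2.77 and 0.49. The second, with 20.1%, set those 2 libraries at opposite ends (-74.3 in WT and 83.3 in Cx43KO). The third component, with 16.9%, set WT 0 h replicate 1 apart at 94.3, the library in which 496 genes were above a level of 1 and below 0.1 in all others.

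The Y-linked gene Ddx3y was at 3.64 and 2.27 in WT 0 h, 0.05 and 0.08 in Cx43KO 0 h, 0.13 and 0.03 in WT 48 h, and 7.31 and 0.22 in Cx43KO 48 h. Kdm5d was at 8.58 and 10.7 in WT 0 h and 7.21 in Cx43KO 48 h replicate 1, and listed at 0 in the other 5 libraries.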
